A study of Homo sapiens with 2 samples.

How the data were processed

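Total RNA of 22Rv1 cells transfected with a negative control siRNA or with KIF15 siRNA was labelled with Cy3 from 0.5 ug of RNA and hybridised to 1 Agilent array per condition, per the labels' protocols. The sequence and number of the siRNAs, the time after transfection and the number of cultures behind each RNA are not given in the sources used here. Groups were taken from the labels, with 1 array in each of 2 groups.

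The deposited scanner files hold intensity values per spot, made with Feature Extraction 11.0.1.1 and protocol GE1_1100_Jul11, per the file headers. The processed signal is a background-subtracted and spatially detrended intensity on a linear scale, not normalized between arrays, per the file headers. The array design, 026652, refers to genome build hg19, per the file headers. A second deposited table holds log2 values per probe, with RMA named in the submitters' processing notes. Its scale was found by comparison with the scanner values: its columns had Spearman correlations across probes of 0.9985 (control) and 0.9982 (KIF15 siRNA) with the log2 scanner values, both had a median of 6.20 and the same quartiles, and the differences between arrays correlated at 0.888. The values are thus on a log2 scale, not centred per gene, and run in the same direction; the steps between scanner and table remain unknown.

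From the scanner files, log2 of the processed signal was averaged over the spots of a probe and the array's 75th percentile over non-control probes was subtracted. Of 44495 spots per array, 1377 were control spots and were left out, as were outlier spots (297 in the control array and 240 in the KIF15 siRNA array). The 75th percentile of the signal was 567.3 in the control array and 541.4 in the KIF15 siRNA array, the median 101.8 and 96.3, and the median of negative control spots 2.68 and 3.15. The number of arrays, 1 per condition, limits the precision: no spread between arrays can be estimated, so no test, p-value or standard error is given for a difference between the conditions. Shuffles, a bootstrap and a permutation test over the genes of these arrays serve to weigh explanations in the closing section.

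Of 34127 probes, 25771 were given 1 gene symbol through their unversioned RefSeq accession in the annotation of GRCh38.p14, 0 matched several and 8356 matched none and were not named. Because the design is on another build, that annotation was used for names and for the order of neighbouring genes, and no coordinates are given. Of 34111 probes with a value on both arrays, 24771 were well above background on both, 1293 in the control array alone, 230 in the KIF15 siRNA array alone and 7817 on neither. A gene's value is the mean over its probes well above background on both arrays. Of 19732 genes with a probe, 15661 were measured, 12086 by 1 probe and 3575 by several. Differences of 2 probes of a gene correlated at r = 0.42 across 3030 genes. For a gene well above background on 1 array alone, the fold is a bound against the higher of the dim probe's own signal and the lowest signal well above background on that array, which was 10.9 in the control array and 12.9 in the KIF15 siRNA array.

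The 24 gene lists, the settings and the rule for named genes were fixed before the data were examined, except the form of normexp. That form, on which the naming rule also relies, was chosen after seeing the data, as described below. The lists were androgen response, androgen repressed, hormone pathway regulators, mitotic spindle and kinesins, G2/M phase, G1/S and DNA replication, p53 targets, interferon response, ATF4 and unfolded protein response, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, proteasome and USP14, heat shock chaperones, glucocorticoid response, immediate early genes, NF-kB and inflammatory, prostate luminal, basal epithelial, neuroendocrine, mesenchymal and immune markers, MYC targets, and housekeeping. Each list was described by its members at least 1.5-fold higher or lower, its median log2 difference, and the percentile of that median among 10000 random lists of the same size drawn from 20 bins of mean signal. A list was said to stand apart below the 2.5 or above the 97.5 percentile.

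Genes were named by this rule: KIF15; the 12 highest and 12 lowest differences among 11689 genes with an approved symbol, a mean signal above the 25th percentile and, for the named ones, at least 2-fold the same way under normexp; the 4 largest bounds in each direction; up to 4 members of each list with the largest differences, of which some are given; and KIF11, KLK3, KLK2, TMPRSS2, FKBP5, USP14, MKI67 and CDKN1A. Some single-gene results under this rule are not reported here. KIF15 is itself among the 12 lowest. Any other gene is said to have been named after its value was seen.

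The alternatives were normexp background correction (offset 50) with quantile normalization, the array median in place of the 75th percentile, quantile normalization, a loess of the difference on the mean (span 0.3), 3 other probe filters, the brightest probe per gene, the deposited log2 table, a 1.5-fold limit for genes, a 2-fold limit for list members, and random lists not matched on signal. Normexp was run on the median spot and background intensity in the deposited files, a choice made after seeing the data, because these files hold no mean spot signal. Counts of list and family members under normexp were likewise added after seeing the data. The normexp offset of 50 draws differences at dim probes toward 0 whatever their source, so a smaller normexp value there is no check on noise. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1, and figures matplotlib 3.10.9.

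The procedure was tested on data simulated for the comparison of KIF15 siRNA with control siRNA over 16205 genes. The simulated noise was the same for every probe, a little above the median between repeat spots, with none between cultures. Simulated folds of 1.5, 2, 3 and 4 were recovered with medians of 1.48, 2.02, 2.91 and 4.06, and 2.0%, 54.0%, 100.0% and 100.0% of these genes passed 2-fold. No unchanged gene did. With noise this small that outcome was set by the simulation, so it gives no rate of false 2-fold calls at noisier probes. On the arrays themselves the SD of a single-spot difference had a 95th percentile of 0.947. A list of 28 genes lowered by 0.4 had a median of -0.43 (percentile 0), and 4.0% of 200 lists drawn at random from all simulated genes stood apart. With small independent noise these outcomes were set by the simulation too. They give no detection or false-call rate for the real lists, whose members may vary together.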

Results

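Gene expression was measured in 22Rv1 cells, a castration-resistant human prostate carcinoma line, after transfection with a negative control siRNA or with siRNA against KIF15, a kinesin motor of the mitotic spindle. The series is concerned with KIF15 and resistance to enzalutamide, an antiandrogen drug. The comparison addresses which transcripts differed between KIF15-depleted and control cells. Each condition was measured on 1 single-colour Agilent array, so no difference between the conditions has a replicate check or a test, and the values describe these 2 arrays. Both arrays lay on the same slide and scan. In the control siRNA array 78.3% of 43118 non-control spots were well above background, against 75.4% in the KIF15 siRNA array, and no spot was saturated. In all, 15661 genes were measured on both arrays. Folds and log2 differences are KIF15 siRNA over control siRNA after each array was scaled to its 75th percentile.

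KIF15 itself was 4.81-fold lower in the KIF15 siRNA array, at 20.8% of the control level. Its log2 signal relative to the array's 75th percentile was 0.59 in the control and -1.68 after KIF15 siRNA, a difference of -2.27 at its single probe, A_23_P80902, which was printed in 1 spot. The difference was the third lowest of all 15661 genes. KIF11, the other kinesin that drives spindle pole separation, was 1.18-fold lower. The only error the design gives is technical. Among 828 probes printed in 10 spots, the SD of a single-spot difference had a median of 0.099 and a 95th percentile of 0.947 on the log2 scale, the latter close to a 2-fold difference. Different probes of a gene scattered about their gene's mean difference with an SD of 0.28 over 3575 genes.

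Most transcripts had similar levels on both arrays, and a small set differed by 2-fold or more. Of the 15661 genes, 107 were at least 2-fold higher and 128 at least 2-fold lower in the KIF15 siRNA array, and 91.7% lay within 1.5-fold. The median log2 difference of all genes was 0.033, with an SD across genes of 0.35. Across genes, which are not independent replicates, Pearson's r between the arrays was 0.991. The number of genes past 2-fold depended on the processing: in the setting called normexp here, which combines the median spot signal, a normexp background correction with an offset and quantile normalization, 37 genes were at least 2-fold higher and 65 lower. The differences of 2 probes of a gene correlated at r = 0.42 across 3030 genes.

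**Figure D1:**
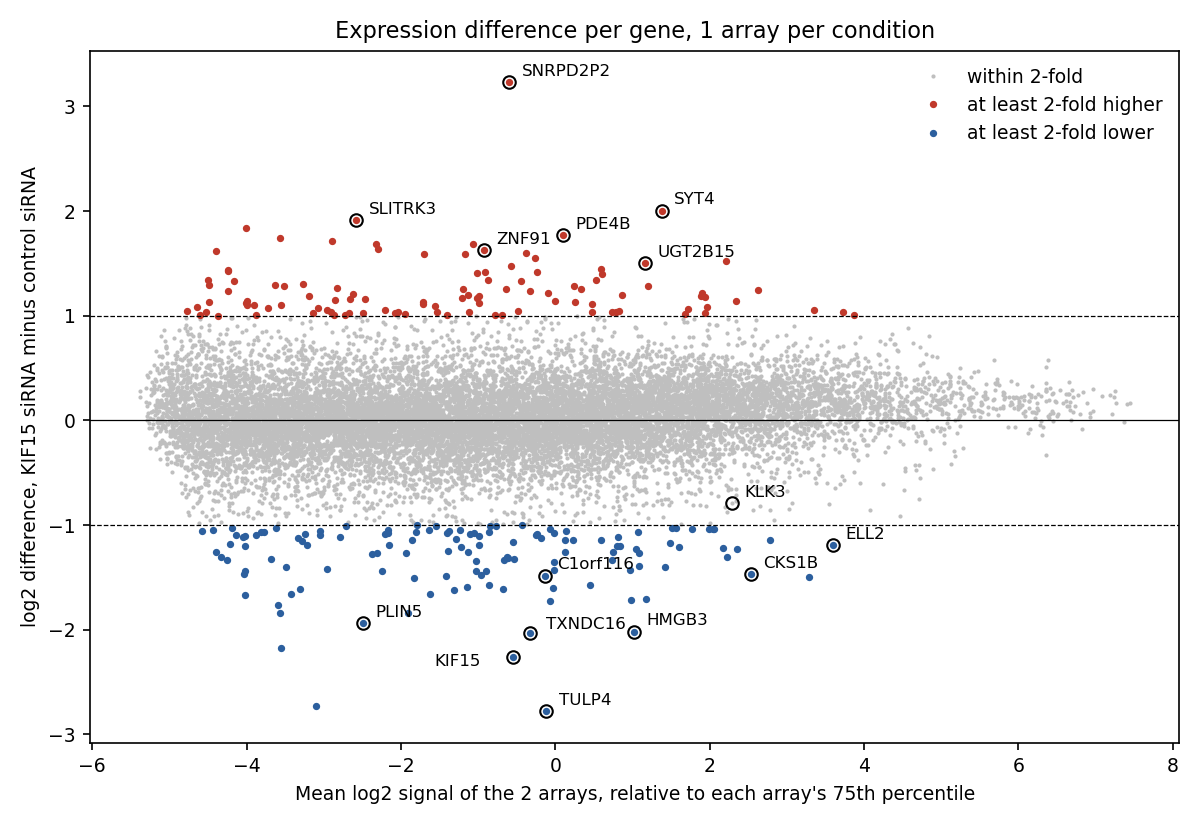
Log2 difference between the arrays (KIF15 siRNA minus control siRNA, vertical axis) against the mean log2 signal of both arrays relative to each array's 75th percentile (horizontal axis), 1 point per gene for 15661 genes. Red points are the 107 genes at least 2-fold higher and blue points the 128 genes at least 2-fold lower; KIF15 lies at -2.27 and KLK3 at -0.79.

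The gene with the highest difference was SNRPD2P2, a pseudogene of the spliceosomal gene SNRPD2, at 9.39-fold higher in the KIF15 siRNA array, with a log2 difference of 3.23 against 2.58 with normexp. Whether its probe also binds the parent gene's transcript was not tested. SYT4, a synaptotagmin of secretory vesicles, was 4.01-fold higher. SLITRK3, a neuronal transmembrane protein, was 3.77-fold higher, with a log2 difference of 1.91 against 1.18 with normexp, and PDE4B, a cAMP phosphodiesterase, 3.41-fold. UGT2B7 was 3.22-fold and UGT2B11 2.94-fold higher; both belong to the UDP-glucuronosyltransferase 2B family, whose close sequence similarity leaves the assignment to single members uncertain. The same applies to ZNF91, a KRAB zinc-finger repressor, at 3.08-fold. AGTR1, the angiotensin II type 1 receptor, was 3.02-fold higher, and MESD, a chaperone of LDL receptor-related proteins, 3.03-fold. TCIM was 3.22-fold and PGM2L1 3.11-fold higher, and TEX19 was higher by 1.59 on the log2 scale.

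Among the genes lowest in the KIF15 siRNA array, TULP4, a tubby-like protein, was 6.87-fold lower, a larger difference than that of KIF15. TXNDC16, a thioredoxin-domain protein, was 4.10-fold lower. HMGB3, an HMG-box chromatin protein, was 4.05-fold lower, with its 2 probes at -2.21 and -1.82 on the log2 scale. PLIN5, a lipid droplet protein, was 3.83-fold lower, with a log2 difference of -1.94 against -1.19 with normexp, and MAD2L2, the REV7 subunit of translesion DNA polymerase zeta, 3.30-fold. PIGX, of GPI anchor synthesis, was 3.29-fold lower, and HACD2, a dehydratase of very long chain fatty acid elongation, 3.08-fold. SLC66A3 was 3.17-fold lower, with its 2 probes at -2.13 and -1.20, and CHIC2, measured in 10 spots, was 3.05-fold lower. The histone gene H4C15 was 3.58-fold and the ribosomal RNA gene RNA18SN5 3.26-fold lower; both have near-identical copies, so these values cannot be assigned to a single gene.

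A further 657 genes were well above background on a single array and have only a bound. Of these, 539 were measured in the control array, 24 of them at least 2-fold lower in the KIF15 siRNA array by their bound. The other 118 were measured in the KIF15 siRNA array, 18 of them at least 2-fold higher. Detection differed between the arrays as a whole. In the control array 26064 probes were well above background, against 25001 in the KIF15 siRNA array. The lowest signal well above background was 10.9 and 12.9. The counts of 539 and 118 were not adjusted for this, so their imbalance is not read as a loss of expression. MMP2, a gelatinase, was at least 6.74-fold lower and KRT80, an epithelial keratin, at least 2.92-fold lower. CUTALP and RPGRIP1L were at least 3.62-fold and 2.91-fold lower. On the other side, GAB3, an adaptor protein, was at least 5.77-fold higher, CPED1 at least 3.38-fold, REDIC1 at least 3.29-fold and ZNF876P at least 3.15-fold. All these bounds are for the main processing, with the signal of the other array near background, and normexp values are not given for them.

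Genes induced by androgen were lower in the KIF15 siRNA array as a group. Of 28 measured androgen response genes, 13 were at least 1.5-fold lower, none was at least 1.5-fold higher and 15 lay between; 25 had a difference below 0. KLK3, which encodes prostate-specific antigen, was 1.73-fold lower, KLK2 1.54-fold, and FKBP5, an HSP90 co-chaperone, 1.56-fold. The 5 members at least 2-fold lower were C1orf116 at 2.80-fold, the methyltransferase GNMT at 2.40-fold, the elongation factor ELL2 at 2.29-fold, the Mediator subunit MED28 at 2.28-fold and NDRG1 at 2.05-fold; NDRG1 was named after its value was seen. With normexp 10 members were at least 1.5-fold lower and 3 at least 2-fold lower; GNMT, MED28 and KLK2, at log2 differences of -0.77, -0.72 and -0.34, were among those that no longer passed the limit they had passed. TMPRSS2 was 1.21-fold lower. The 3 members above 0, also named after their values were seen, were PTGER4 at 1.36-fold, ACSL3 at 1.03-fold and PMEPA1 at 1.02-fold. The median log2 difference of the list was -0.43. None of 10000 random lists of the same size and signal had so low a median, and the middle of the random medians was 0.062. In all 10 alternative settings run on the lists the percentile was 0, with medians from -0.58 to -0.30.

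**Figure D2:**
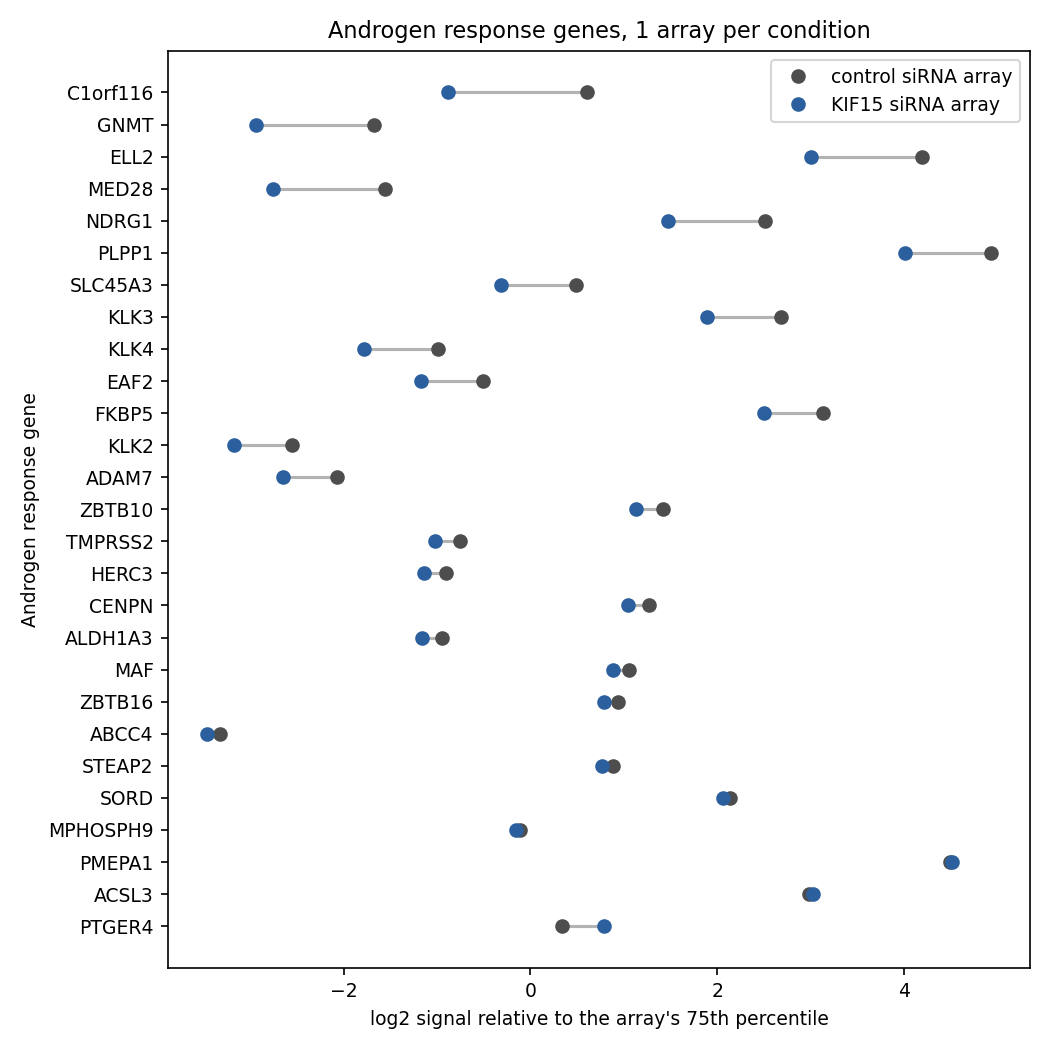
Log2 signal relative to the array's 75th percentile (horizontal axis) of the measured androgen response genes, with 1 member not drawn, in the control siRNA array (grey) and the KIF15 siRNA array (blue), 1 array each, ordered by their difference. The blue point lies to the left of the grey one in all genes drawn except 3, PTGER4, ACSL3 and PMEPA1; levels of different genes are not comparable, because each has its own probe.

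The list of genes repressed by androgen had a median above 0. Of 9 measured, 2 were at least 1.5-fold higher, 1 at least 1.5-fold lower and 6 between. UGT2B15, a steroid glucuronosyltransferase with close relatives on the array, was 2.84-fold higher and the receptor tyrosine kinase gene MET 1.87-fold higher, whereas TNFRSF19 was 1.68-fold lower and BCHE, butyrylcholinesterase, 1.39-fold lower; the TNFRSF19 probe was dim, and its log2 difference was -0.22 with normexp. The list median was 0.31, at the 99.1 percentile of matched random lists; it was 93.1 with the brightest probe of each gene and 96.3 with probes above background on either array, both inside the central range. The median was 0.18 with normexp and 0.49 with a stricter filter, which left 5 genes. UGT2B15 and MET lie in sets, described below, that were mostly higher: the UGT2B family and the run from SAMTOR to AASS. Without them no member was at least 1.5-fold higher. FOLH1 (0.474), PCDH11X (0.377), DDC (0.312) and PRUNE2 (0.095) were above 0, and PEG3 (-0.181), BCHE (-0.479) and TNFRSF19 (-0.746) below. All but the last 2 were named after their values were seen. The middle of these values is that of PRUNE2, so the list median leaned on UGT2B15 and MET. Of 38 hormone pathway regulators, a list of cofactors, chaperones, ligases and steroid enzymes, 2 were at least 1.5-fold higher, 4 at least 1.5-fold lower and 32 between. The splicing factor gene SRSF1 was 2.14-fold lower, the steroid dehydrogenase gene HSD3B1 1.97-fold and CCND1, cyclin D1, 1.82-fold, while UGT2B15, listed here too, was higher. HSD3B1 lay near background, and its log2 difference of -0.98 was -0.20 with normexp. The median of these regulators was -0.079, at the 0.34 percentile, and it no longer stood apart in 5 of 10 alternative settings; with a stricter filter on spots and signal it was 0.043. USP14, a proteasomal deubiquitinase, was 1.24-fold lower. The 34 proteasome genes including it had 0 members past 1.5-fold in either direction and a median of 0.15, at the 59.4 percentile; against random lists not matched on signal it was at 97.6. In that list PSMD1 was 1.36-fold lower and PSMD8 1.30-fold higher.

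Genes of the glucocorticoid response were lower as a group as well. Of 17 measured, 2 were at least 1.5-fold lower, none was at least 1.5-fold higher and 15 lay between, with a median of -0.13 at the 0.87 percentile and at 2.55, no longer apart, against random lists not matched on signal. The median was -0.25 with normexp and -0.23 after a loess. TSC22D3 was 1.78-fold lower and the metallothionein MT2A 1.54-fold. CDKN1C, a cyclin-dependent kinase inhibitor, was 1.46-fold lower.

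Lists of proliferation genes had medians slightly below 0, with few members past 1.5-fold. Relative to the middle of their matched random medians, the G2/M and G1/S medians lay at -0.15 and -0.14 on the log2 scale, and that of the housekeeping genes at a similar -0.14. Of 29 mitotic spindle and kinesin genes, which exclude KIF15, 1 was at least 1.5-fold lower and 28 lay within 1.5-fold; the median was -0.11, at the 0.49 percentile and at 4.29, no longer apart, with normexp. The member past 1.5-fold was the mitotic kinase AURKA, 1.93-fold lower. TPX2, which activates that kinase, was 1.45-fold lower and BIRC5, survivin, 1.41-fold. Of 29 G2/M genes, 1 was at least 1.5-fold lower and 28 lay between, with a median of -0.047 at the 0.70 percentile. This median depended on the scaling: it was -0.17 with normexp and after a loess, -0.15 with quantile normalization and -0.027 with scaling to the array median. That gene was CKS1B, a subunit of cyclin-dependent kinases, which was 2.77-fold lower with both of its probes below 0. The transcription factor gene FOXM1 was 1.40-fold and the proliferation marker MKI67 1.35-fold lower. Of 31 G1/S and replication genes, 2 were at least 1.5-fold lower and 29 between, with a median of -0.056 at the 1.40 percentile; it was -0.12 with normexp and -0.13 after a loess. CCNE2, cyclin E2, was 1.68-fold lower and the flap endonuclease FEN1 1.52-fold, the latter under 1.5-fold with normexp, at -0.49 on the log2 scale, whereas E2F1 was 1.37-fold higher. Against random lists not matched on signal, the G2/M list was at the 10.96 percentile and the G1/S list at 8.04, so neither stood apart there.

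MYC targets, a list of mainly nucleolar and ribosome biogenesis genes with some metabolic enzymes, were higher as a group. Of 30 measured, 2 were at least 1.5-fold higher, none was at least 1.5-fold lower and 28 lay between; 25 were above 0. NOLC1, a nucleolar phosphoprotein, was 2.03-fold higher and POLR3G, a subunit of RNA polymerase III, 1.68-fold; BOP1 was 1.44-fold higher, and FBL, fibrillarin, was higher by 0.58 on the log2 scale. The list median was 0.25, at the 99.6 percentile. It was 0.13 with normexp, 0.14 after a loess and 0.16 with quantile normalization, and the list stood apart in all 10 alternative settings. The middle of its matched random medians was 0.11, so the list lay 0.14 above it, a distance similar in size to that of the housekeeping genes, -0.14.

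Lists of cell type markers stood apart in both directions. Of 20 prostate luminal markers, 2 were at least 1.5-fold lower and 18 between; ACP3, prostatic acid phosphatase, was 2.03-fold lower, with a log2 difference of -1.03 against -0.47 with normexp, while DPP4 was 1.47-fold higher. The luminal median was -0.057, at the 1.36 percentile, and it no longer stood apart with the brightest probe of each gene, at 2.76, or without matching on signal, at 12.4; the median was -0.13 with normexp and -0.17 after a loess. Of 10 basal epithelial markers, 3 were at least 1.5-fold higher and 7 between, with a median of 0.27 at the 99.4 percentile and at 95.8, no longer apart, without a filter on dim probes. The keratin KRT6A was 1.73-fold, LAMB3, a laminin chain, 1.60-fold and S100A2 1.60-fold higher; with normexp 1 basal marker passed 1.5-fold, KRT6A being at 0.32 and LAMB3 at 0.50 on the log2 scale, and the basal median was 0.18. Of 16 mesenchymal markers, 2 were at least 1.5-fold higher, 1 at least 1.5-fold lower and 13 between, with a median of 0.29 at the 99.9 percentile and apart in all 10 settings; the median was 0.18 with normexp and 0.21 without a filter on dim probes. PDGFRB was 1.87-fold and fibronectin, FN1, 1.57-fold higher, both at dim probes, whereas S100A4 was 1.88-fold lower. With normexp no mesenchymal marker was at least 1.5-fold higher, PDGFRB being at 0.38 and FN1 at 0.26 on the log2 scale. MMP2, on the mesenchymal list too, was lower by its bound and is outside these counts. Of 14 neuroendocrine markers, 2 were at least 1.5-fold higher, 1 at least 1.5-fold lower and 11 between; besides SYT4, PEG10 was 1.93-fold higher and FOXA2 1.84-fold lower, the latter at -0.37 on the log2 scale with normexp. The neuroendocrine median was 0.085, at the 79.3 percentile. Of 18 leukocyte markers, 1 was at least 1.5-fold higher, CD68 at 1.61-fold (log2 difference 0.30 with normexp), and 17 lay between, with a median of 0.033 at the 61.7 percentile.

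**Figure D3:**
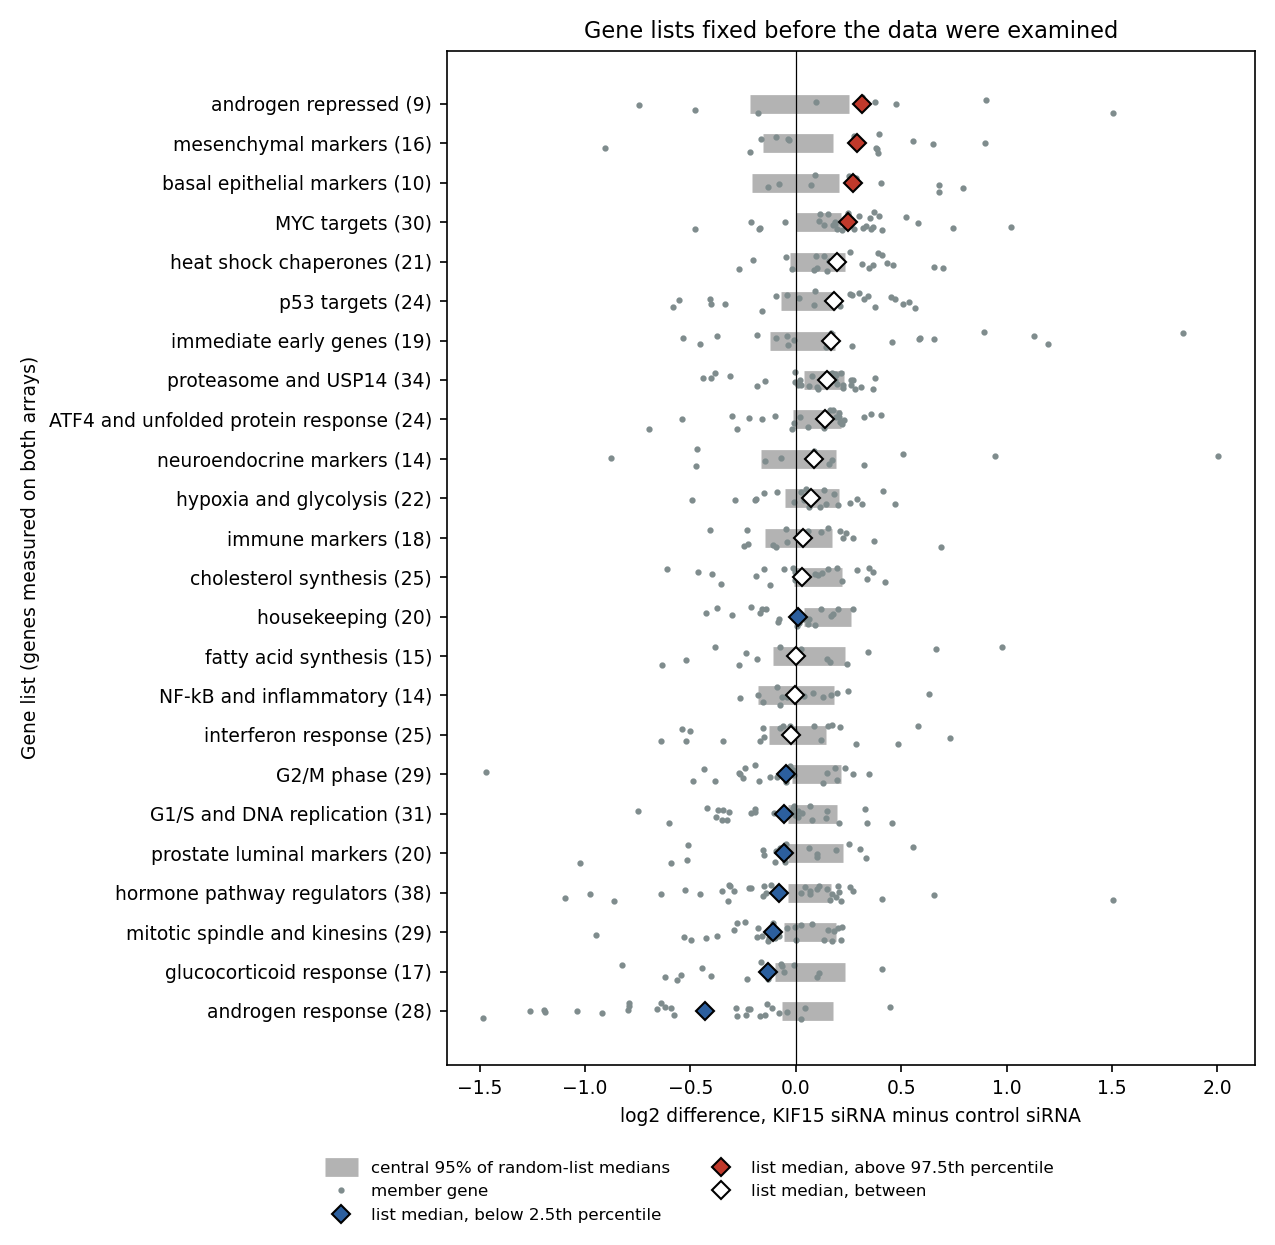
Log2 difference, KIF15 siRNA minus control siRNA (horizontal axis), of the member genes (grey points) and the median (diamond) of the 24 gene lists, with the number of measured genes in brackets; grey bars span the central 95% of medians of 10000 random lists matched on size and signal. Blue diamonds are the 8 lists below the 2.5 percentile, with androgen response lowest at -0.43, and red diamonds the 4 lists in the top 2.5% of random medians.

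Stress and metabolic lists did not stand apart at the matched percentiles. Of 19 immediate early genes, 6 were at least 1.5-fold higher and 13 lay between, including EGR2 at 3.58-fold, EGR1 at 2.29-fold, FOS at 2.19-fold and FOSB at 1.86-fold; the median was 0.17, at the 96.0 percentile, and at 99.5 with normexp. EGR2 and FOSB were read near background: with normexp the log2 differences were 0.70 for EGR2, 1.16 for EGR1, 0.81 for FOS and 0.22 for FOSB, and 4 members passed 1.5-fold. Of 21 heat shock chaperones, 2 were at least 1.5-fold higher and 19 between, SERPINH1 at 1.62-fold and FKBP4 at 1.58-fold, the latter at 0.58 on the log2 scale with normexp, just under 1.5-fold; the median of 0.20 was at the 92.3 percentile and in the top 2.5% in 6 of 10 alternative settings. Of 24 p53 targets, 0 passed 1.5-fold in either direction. Their median was 0.18, at the 97.2 percentile, and at 98.0 with quantile normalization and 98.5 without matching on signal. The cell cycle inhibitor CDKN1A had a log2 difference of -0.58, just short of that limit, and FDXR, ferredoxin reductase, was 1.48-fold higher.

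The 25 interferon response genes had 1 member at least 1.5-fold higher, IFIT2 at 1.66-fold, 1 lower, IRF7 at 1.56-fold, and 23 between, with a median of -0.021 at the 32.0 percentile. Of 24 genes of the ATF4 and unfolded protein response, PPP1R15A was 1.62-fold lower and 23 lay between, with a median of 0.14 at the 73.1 percentile. Among 25 cholesterol synthesis genes SC5D was 1.53-fold lower and 24 lay between; the median was 0.032, at the 10.6 percentile. Of 15 fatty acid synthesis genes, 2 were at least 1.5-fold higher, 1 at least 1.5-fold lower and 12 between. ME1 was 1.97-fold and GPAM 1.59-fold higher, and ELOVL6 1.55-fold lower. The median was 0.00060, at the 20.9 percentile. The 22 hypoxia and glycolysis genes had 0 members past 1.5-fold and a median of 0.074 at the 44.1 percentile. Of 14 NF-kB and inflammatory genes, RELB was 1.55-fold higher and 13 lay between. Their median was -0.0017, at the 49.5 percentile, and their mean had the opposite sign, at 0.044. The medians of the cholesterol, fatty acid, hypoxia, NF-kB and leukocyte lists lay on both sides of 0 across the alternative settings, so none of them has a direction. With normexp no interferon, ATF4 or cholesterol gene passed 1.5-fold: IFIT2 was at 0.36, IRF7 at -0.45, PPP1R15A at -0.43 and SC5D at -0.45 on the log2 scale. Of the fatty acid genes, ME1, at 0.38, and ELOVL6, at -0.57, did not pass, whereas GPAM, at 0.63, did.

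Housekeeping genes had 0 of 20 members past 1.5-fold. PPIA was 1.34-fold and SDHA 1.30-fold lower, with their probes spread from -1.17 to -0.21 and from -0.74 to 0.25 on the log2 scale. The median was 0.010, the mean -0.038 and the percentile 0.75, because genes as bright as these had random medians around 0.15. The sign of the median turned negative under normexp, quantile and loess normalization, with a stricter filter and in the deposited normalized values, and the list did not stand apart with the brightest probe of each gene or without matching on signal. In all, 12 of the 24 lists stood apart, 8 low and 4 high, where 1.2 are expected by chance for independent genes. The lists share members, and the random lists ignore correlation between genes.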

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

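In the weighing of the 2-fold differences below, the tests were set before their results were seen.

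Signal outside the named genes came from the 4851 probes without a gene symbol here that were well above background on both arrays. Of these, 26 were at least 2-fold higher and 18 at least 2-fold lower in the KIF15 siRNA array, 0.907% of them, with the largest differences 3.85-fold higher and 5.13-fold lower. Among the 15661 measured genes with a symbol the share was 1.501%. That is a share of genes, whose values are means over their probes, so the shares are not directly comparable.

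The 235 genes at least 2-fold apart rest on 1 array for each condition. Spot-to-spot noise is argued against as their whole source: of 828 probes averaged over 10 spots, 13 (1.57%) were at least 2-fold apart, against 1.41% of single-spot probes of the same signal, where noise would have made the first share far smaller. A trend of the difference with signal is argued against too, since 220 of the 235 genes stayed at least 2-fold apart the same way after a loess. A position effect over large areas of the array is argued against, because the medians of 70 blocks ran only from -0.092 to 0.072. After they were subtracted, 225 of 235 stayed at least 2-fold apart the same way. Blocks of 38 rows by 17 columns cannot show a local fault at single spots, and the processed signal was already spatially detrended. Faults at single spots therefore remain open. With normexp, which changes the signal column, background correction and normalization together, 97 of the 235 stayed at least 2-fold apart the same way. The normexp offset of 50, added to every signal, draws differences at dim probes toward 0 whatever their source. The drop to 97 thus cannot tell real differences at dim probes from noise. Quantile normalization alone kept 222 of the 235, and the stricter filter on spots and signal kept 157 of the 161 it measured. How far the other differences rest on noise at dim probes was not tested, so this source remains open. Depletion of KIF15, effects of the siRNA on other transcripts and differences between the cultures or RNA preparations also remain open and untested with 1 array each.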

How the results depend on the processing

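The alternatives were planned before the data were examined, except normexp on the median spot signal, which was chosen after; the planned normexp on the mean signal was not run, because the files hold no such column. No paired analysis was possible because each group has 1 array and no difference between the groups comes from a test, and leaving out a replicate is likewise impossible. KIF15 was lower in every setting, from -2.28 to -1.97, the latter with normexp. Normexp gave 37 genes at least 2-fold higher and 65 lower, against 107 and 128; this setting changes the signal column, the background correction and the normalization together, and which of them moved the counts was not tested, though quantile normalization alone gave 109 and 127. Probes above background on either array gave 226 genes lower, and no filter on dim probes gave 272 higher and 318 lower, as more dim genes were counted. A 1.5-fold limit gave 672 higher and 621 lower. Of the 235 genes at least 2-fold apart, 97 kept this the same way under normexp, 220 under loess, 222 under quantile normalization and 228 in the deposited log2 values. The androgen response median of -0.43 was -0.33 with normexp, -0.58 with probes above background on either array, -0.30 without a filter and -0.57 with the stricter filter. The percentile stayed at 0. The median of -0.43 lies in a gap between ADAM7 at -0.578 and ZBTB10 at -0.285, both named after their values were seen. It can thus move far with 1 gene. With probes above background on either array, 29 genes were measured in place of 28 and the median fell on the value of ADAM7. The cause of the other shifts was not tested. The housekeeping median of 0.010 reversed to -0.12 with normexp, -0.097 with quantile normalization, -0.13 with loess, -0.062 with the stricter filter and -0.11 in the deposited log2 values; the first 3 remove the higher differences of bright genes, and the cause was otherwise not tested. The hormone pathway regulators' median of -0.079 reversed to 0.043 with the stricter filter, which left 33 of 38 genes; the cause was not tested. Between 9 and 13 lists stood apart in the settings run. Signal over background limits what can be seen: 7817 probes were above it on neither array.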

Other observations

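The families and runs of genes in this part, and all tests on them and on the androgen response, were chosen only after their values were seen, except the loess, which was a planned setting.

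Several families had most of their members on the same side. Some of their members, UGT2B15 among the UGT2B genes and KLK2, KLK3 and KLK4 among the kallikreins, are also on the lists above. All 4 measured UGT2B genes, which conjugate steroids and other lipophilic compounds with glucuronic acid, were higher in the KIF15 siRNA array, with a median log2 difference of 1.53; UGT2B10, not named above, was 2.54-fold higher. The median was 1.29 with normexp. Of 40 protocadherins, cell adhesion genes of clustered loci, 33 were above 0, with a median of 0.23, and 6 were at least 1.5-fold higher. PCDHA1 was 2.71-fold higher, but near background, and its log2 difference was 0.43 with normexp. Of 62 histone genes, 51 were below 0 and 7 at least 1.5-fold lower, with a median of -0.26. H1-3, a linker histone, was 2.27-fold lower at a dim probe and at -0.31 on the log2 scale with normexp. Of 9 kallikreins, secreted serine proteases that include KLK3, 4 were at least 1.5-fold lower and 1 at least 1.5-fold higher, KLK1 at 1.51-fold, with a median of -0.41. The lower ones include KLK2, KLK3 and KLK4 of the androgen response list, so this family is no separate result. The kallikreins not on that list lay on both sides of 0. KLK1 (0.595), KLK8 (0.227) and KLK11 (0.197) were above it, and KLK5 (-0.678), KLK15 (-0.412) and KLK6 (-0.384) below. The directions of these medians held in every setting run, but with normexp they were smaller, at 0.14 for protocadherins, -0.17 for histones and -0.18 for kallikreins. Under normexp 0 protocadherins were at least 1.5-fold higher, 3 histone genes were at least 1.5-fold lower, and of the kallikreins KLK3 alone passed 1.5-fold; KLK2 was at -0.34, KLK4 at -0.58 and KLK1 at 0.45 on the log2 scale. Members of these families have similar sequences, and cross-hybridisation was tested in none of them. The 77 ribosomal protein genes had a median of 0.16, at the 42.7 percentile of signal-matched random lists, and -0.020 after loess, so they have no direction.

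Along the gene order of GRCh38.p14, the 20 consecutive measured genes with the highest median ran from SAMTOR to AASS and included MET. Their median was 0.50, with 15 of 20 above 0, and 0 of 100 shuffles of gene order within signal bins gave so high a window, the highest reaching 0.48. The median of these genes was 0.34 with normexp. TSPAN12, a tetraspanin, was 2.39-fold, KCND2, a potassium channel, 1.91-fold, ASZ1 1.76-fold and FAM3C 1.64-fold higher; ASZ1 was at 0.40 on the log2 scale with normexp. CAV1, in the same stretch, was 1.05-fold lower. The lowest window held histone genes from H1-2 to H2BC9, with a median of -0.29, and 27 of 100 shuffles reached as low.

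The androgen response genes were lower in the KIF15 siRNA array with a median of -0.43. A trend of the difference with signal is argued against, since the median was -0.46 after a loess. A general lower level of luminal genes is argued against as the whole source, but not as a part. The 19 luminal markers outside the androgen lists had a median of -0.053, above the highest bootstrap median of the androgen response list, -0.14. That comparison left out the spread of these markers, from -1.025 to 0.556. The full luminal list itself stood apart low, at the 1.36 percentile, and its median was -0.17 after the loess. A difference between 2 cultures unrelated to KIF15, such as density or hormone in the medium, cannot be told apart from an effect of KIF15 siRNA, because the series has 1 control array.

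In a run of neighbouring zinc-finger genes from ZNF253 to ZNF254, which includes ZNF91, 24 of 25 were higher in the KIF15 siRNA array, with a median of 0.448, or 0.345 with normexp; ZNF681 was 2.65-fold higher. The 421 other zinc-finger genes were higher too, with a median of 0.098 and 277 above 0, but a general shift is argued against as the whole source: 8 of 1000 shuffles of the differences among all 446, within signal bins, held a run of 25 neighbours with a median as high as 0.448. Chance order is argued against too: the best window of 20 in the run had a median of 0.464, and 1 of 100 shuffles gave a window as high. Cross-hybridisation of 1 transcript with probes of similar genes cannot be told apart from a shared higher level, as the difference had a Spearman rho of -0.155 with control signal across the run's genes (permutation p = 0.471), and probe sequences were not used.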
